A study of Homo sapiens with 36 samples.

How the data were processed

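HEK293T cells transfected with siNC or with small interfering RNA against CHD3, CHD4, CHD5, MBD2 or MBD3 were profiled with an antibody to CTCF, and an input was sequenced for each condition, per the labels' protocols. There were 18 CTCF immunoprecipitates and 18 inputs, 3 of each per condition. Libraries were amplified by PCR and sequenced from both ends, per the labels' protocols. Per the submitters' processing notes, FastQC 0.11.7, Bowtie2 2.3.4, SAMtools 1.9, MACS2 2.1.2, bedtools 2.25.0 and deepTools 3.5.0 were used with the hg19 build. The role and settings of each tool, including filters for duplicates or mapping quality and the peak threshold, were not given in the sources used here.

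The files used were 6 deposited peak lists in the MACS2 narrow-peak layout, each named as the 3 replicates of a condition called together, treatment against control. The columns were taken as the authors' linear fold enrichment at the summit, a ratio over local background, the deposited −log10 of p and −log10 of q, the deposited display score and the summit offset. The score was not used. The smallest −log10 q in the authors' deposited tables was 1.30. Replicates were pooled by the authors before calling, so from these lists replicates could not be compared and no test between conditions was made. Reads or peaks of single replicates were not used here. Lines sharing a start and end, which are several summits of 1 peak, were counted once with the summit of highest fold. Peaks on the 23 chromosomes 1 to 22 and X entered the counts.

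Overlaps were computed with bedtools 2.31.1 and required 1 bp. Control peaks with no overlapping peak in a knockdown list are called missing, and knockdown peaks with no overlapping siNC peak are called added. A missing peak is a peak not called in a pooled list, which depth, enrichment and threshold all affect. Overlap after moving the knockdown peaks by 20000 bp measured coincidental overlap. Merged regions joined overlapping or touching peaks of all 6 lists. Draws permuted missing peaks within deciles of siNC fold, 10000 times for chromosomes, adjacent peaks and density and 1000 times for overlap between knockdowns. Another 1000 draws for density were matched on fold, on the chance of a call at the knockdown's depth in 20 classes, or jointly on siNC pileup and local background in 20 classes each. All draws are descriptions of these lists, not tests between conditions. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

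Read counts per sample were not used here, so depth was read from the lists. For each peak, the summit pileup and local background were solved from the authors' fold and p, taking fold as pileup plus 1 over background plus 1 and p as a Poisson upper tail. A whole-number pileup matched p within 0.01% for 100% of peaks in each list, and for at most 1.99% of peaks when p was shuffled among peaks. The smallest background in a list was taken as its genome-wide fragment coverage, which scales with depth times fragment length and is called depth here, though fragment length and duplicates are not known. The shortest peaks were 178 to 196 bp in the 6 lists. Each siNC pileup was then thinned binomially to the coverage of a knockdown list, and the chance that it still passed that list's smallest −log10 p was used as a weight. This weighting, like leaving out peaks over 1 kb or a whole list, was chosen after the data were seen.

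Alternatives fixed before the data were examined were −log10 q of at least 5 or 10 in both lists, −log10 q of at least 10 in the searched-for list only, reciprocal overlap of 50%, summits within 100 bp, any peak within 1 kb, lists of equal length (the 25358 peaks of smallest p), merging within 500 bp, and all contigs. The rule for named regions, also fixed then, took for each knockdown the 5 siNC peaks of highest fold with no knockdown peak within 1 kb and the 5 knockdown peaks of highest fold with no siNC peak within 1 kb. It also took the 10 strongest siNC peaks, the 10 strongest with no peak of any knockdown within 1 kb, and the 10 regions of highest median rank in all 5 knockdown lists with no siNC peak within 1 kb. The leading ones are printed. Promoter shares, CTCF motif shares and the planned gene lists were not run, because a genome and annotation of hg19 were not used here.

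Overlap counts, the pileup solution, thinning and the draws for density, adjacency and overlap between knockdowns were tested on simulated data. All 7254 dropped and 2000 added peaks were recovered, the pileup was solved for 4895 of 4897 simulated peaks, and 35339 calls were expected after thinning to 0.7 of the depth, against 35366 drawn. Random groups of peaks stood in for the density quintiles. For these groups, adjacency and overlap, no random set lay above the range of the draws and each planted set did. These are checks of the computation only. Thinning was compared with draws from its own model, and the random sets held no link between density and pileup.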

Results

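CTCF, a zinc-finger protein that binds insulators and the anchors of chromatin loops, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in HEK293T, a human embryonic kidney cell line. Cells received a small interfering RNA against 1 of 5 subunits of NuRD, a complex that remodels nucleosomes and removes histone acetyl groups, or a control small interfering RNA (siNC). The targets were the ATP-dependent helicases CHD3, CHD4 and CHD5 and the methyl-CpG-binding-domain proteins MBD2 and MBD3. The series held 36 samples in 12 groups, with 3 CTCF immunoprecipitates and 3 inputs per condition. The values used here were 6 peak lists, 1 per condition, each pooling the 3 replicates, so no spread between replicates exists for any value below and no test between conditions was made. Expression of the targeted subunits was not analysed here. Exact Clopper-Pearson 95% intervals are given for shares and cover counting error only. Fold enrichments and q-values are the authors' own for each peak and rank peaks within 1 list. Positions are hg19, 1-based, and gene annotation of that build was not used here.

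The control list was the longest. It held 36270 peaks on chromosomes 1 to 22 and X, against 34319 for siCHD3, 31451 for siCHD5, 26087 for siMBD2, 25848 for siMBD3 and 25358 for siCHD4. Peaks were narrow in all 6 lists, with median widths from 242 bp (siMBD3) to 304 bp (siNC), and covered 11.6 Mb in siNC and 11.9 Mb in siCHD3 but 6.88 Mb in siMBD3. Background coverage, which scales with sequencing depth times fragment length, differed widely between the lists. The lowest background implied by the fold and p of the peaks was 2.96 fragments per bp in siNC, 1.95 in siCHD5, 1.06 in siCHD4, 0.640 in siMBD2, 0.445 in siCHD3 and 0.374 in siMBD3, so that the siNC background was 7.92 times that of siMBD3. Depth below means this coverage. The strongest control peak lay on chromosome 8 from 62115006 to 62115322 (fold 26.1), followed by chromosome 2 from 139045464 to 139046435 (fold 23.1) and chromosome 2 from 34064953 to 34065306 (fold 22.9).

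**Figure D1:**
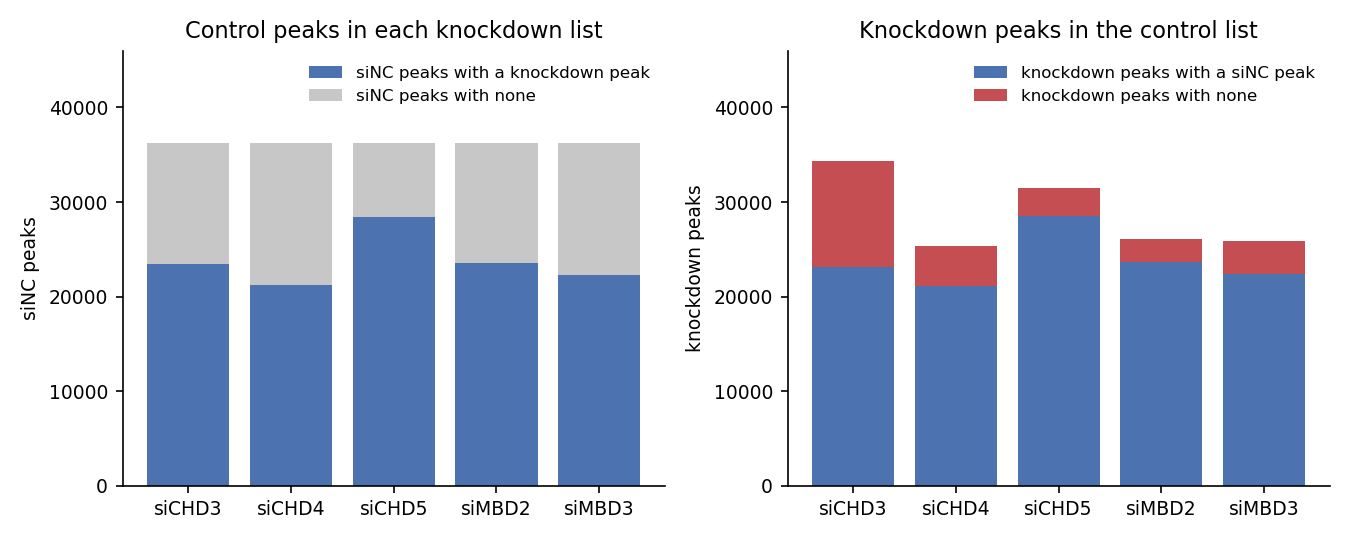
Left, bars give the number of siNC peaks with and without an overlapping peak in each knockdown list; right, bars give the number of peaks of each knockdown list with and without an overlapping siNC peak. The siCHD4 list left 15047 of 36270 siNC peaks without a partner and siCHD5 left 7805, while siCHD3 held 11199 peaks with no siNC partner.

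The siCHD3 list differed from control in both directions. It lacked 12856 of the 36270 control peaks (35.4%, interval 35.0 to 35.9) and held 11199 peaks where control had none (32.6% of its peaks, interval 32.1 to 33.1), the highest share of added peaks among the 5 knockdown lists as deposited. Among the strongest control peaks with no siCHD3 peak within 1 kb were chromosome 7 from 143875529 to 143875857 (fold 16.9), chromosome 8 from 33497671 to 33498001 (fold 16.0) and chromosome 13 from 108974582 to 108974903 (fold 14.4). The strongest added peaks lay on chromosome 10 from 74677264 to 74677913 (fold 58.0), chromosome 20 from 34319854 to 34320069 (fold 50.4) and chromosome 5 from 126478905 to 126479532 (fold 35.7). What these regions contain, such as exons, was not analysed here. Added peaks reached into the strong part of this list: 79.8% of its weakest 10% of peaks and 11.9% of its strongest 10% by fold had no control partner (interval of the latter 10.8 to 13.0). Control peaks weighted by their chance of being called at the siCHD3 depth gave 6591 missing, 27.2% of 24267, and lists of equal length gave 7678, 30.3% of 25358. With −log10 q of at least 10 in both lists, 16844 of 28503 control peaks were missing (59.1%, against 29.0% with the threshold on the control list only) and 2597 added peaks were left. That setting also drops weaker siNC partners of siCHD3 peaks. With the threshold on the siCHD3 list only, 1264 of 14169 peaks were added (8.92%).

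Among the lists as deposited, siCHD4 lacked the most control peaks, 15047 of 36270 (41.5%, interval 41.0 to 42.0), and 4258 of its peaks were added (16.8%, interval 16.3 to 17.3). The loss reached the strongest decile of control peaks, of which 17.9% had no siCHD4 peak (interval 16.7 to 19.2). Strong control peaks without a siCHD4 peak within 1 kb lay on chromosome 8 from 33497671 to 33498001 (fold 16.0), the region also missing in siCHD3, on chromosome X from 86554566 to 86555298 (fold 15.1) and on chromosome 16 from 13547801 to 13548219 (fold 14.8). Of the 5 strongest added peaks, the regions on chromosome 20 from 34319854 to 34320067 (fold 16.4) and chromosome 10 from 74677264 to 74677907 (fold 15.5) were also the leading added regions of siCHD3, and chromosome 1 from 40598884 to 40599105 (fold 16.1) overlapped a leading added region of siMBD3. Weighting by the chance of a call at the siCHD4 depth left 12145 control peaks missing, 38.1% of 31850. Lists of equal length gave 7727 missing (30.5% of 25358) and 7741 added, the latter 30.5% of peaks in both siCHD4 and siCHD3. Numbers missing and added are nearly equal there by construction. The siCHD4 list stays whole while the siNC list is cut to 25358 peaks, so the rise in added peaks from 4258 follows from the cut. With −log10 q of at least 10 in both lists, 900 added peaks were left, against 276 with the threshold on the siCHD4 list only. At 10 in both lists, the share missing was higher in siMBD3 (61.2%) than in siCHD4 (59.4%, against 34.4% with the threshold on the control list only).

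The siCHD5 list lacked the fewest control peaks. It missed 7805 control peaks (21.5%, interval 21.1 to 21.9), the lowest share of the 5 knockdown lists under every alternative computed, and added 2960 (9.41% of its peaks, interval 9.09 to 9.74). Losses fell on weak peaks: 55.4% of the weakest decile of control peaks were missing and 4.69% of the strongest decile (interval 4.02 to 5.43). The strongest control peak without a siCHD5 peak within 1 kb was on chromosome 1 from 8926345 to 8926571 (fold 14.9), followed by chromosome 11 from 118964726 to 118965023 (fold 12.4). Added peaks were led by chromosome 18 from 20611444 to 20611841 (fold 16.5) and chromosome 2 from 189889970 to 189890282 (fold 14.1), and both regions were called in all 5 knockdown lists. Background coverage was the highest of the knockdown lists, and weighting by the chance of a call left 6876 control peaks missing, 19.6% of 35163. Lists of equal length gave 3339 (13.2%), and −log10 q of at least 10 in both lists gave 5174 (18.2%, against 9.38% with the threshold on the control list only). The threshold on both lists left 2083 added peaks (8.20%), a higher share than in siMBD2 (2.48%), siMBD3 (2.77%) or siCHD4 (7.24%). However, it kept 80.8% of siCHD5 peaks but 55.3% in siMBD2, 44.0% in siMBD3 and 49.0% in siCHD4, so these shares are not alike. In the strongest decile of each list by fold the order was reversed, with 0.445% added in siCHD5, 0.767% in siMBD2, 0.967% in siMBD3 and 4.69% in siCHD4. With the threshold on the siCHD5 list only, 900 were added (3.54%).

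The siMBD2 list lacked 12672 control peaks (34.9%, interval 34.4 to 35.4) and added 2426 (9.30% of its peaks, interval 8.95 to 9.66), the smallest number of added peaks in the lists as deposited. Of the weakest decile of control peaks 68.5% were missing, against 13.2% of the strongest decile (interval 12.1 to 14.3). Missing control peaks were led by chromosome 18 from 66514545 to 66514905 (fold 17.2), chromosome 4 from 188892033 to 188892352 (fold 16.5) and chromosome 13 from 108974582 to 108974903 (fold 14.4), the last also missing in siCHD3 and siMBD3. The strongest added peak was on chromosome 2 from 30936940 to 30937210 (fold 14.3). Weighted by the chance of a call at the siMBD2 depth, 6769 control peaks were missing, 24.6% of 27495, and lists of equal length gave 4857 missing (19.2%) and 4798 added. With −log10 q of at least 10 in both lists, 50.7% of control peaks were missing, against 23.1% with the threshold on the control list only. Added peaks were then 358, against 168 with the threshold on the siMBD2 list only.

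In the siMBD3 list, 13970 control peaks were missing (38.5%, interval 38.0 to 39.0) and 3476 peaks were added (13.4%, interval 13.0 to 13.9). The share missing fell from 67.9% in the weakest decile of control peaks to 17.2% in the strongest decile (interval 16.0 to 18.4). Missing control peaks were led by chromosome 14 from 42069763 to 42070131 (fold 16.3), chromosome 13 from 108974582 to 108974903 (fold 14.4) and chromosome 2 from 75468876 to 75469217 (fold 14.0), and the last was missing in siMBD2 as well. Added peaks were led by chromosome 2 from 105854460 to 105854861 (fold 14.8), chromosome 4 from 165118016 to 165118355 (fold 14.2) and chromosome 1 from 40598915 to 40599105 (fold 14.1). Background coverage was the lowest of the 6 lists, and weighting by the chance of a call left 5249 peaks missing, 24.8% of 21185. Lists of equal length gave 6147 missing (24.2%) and 6072 added. A −log10 q of at least 10 in both lists gave 61.2% missing, against 28.3% with the threshold on the control list only. It left 315 added, against 158 with the threshold on the siMBD3 list only.

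Thinning the control summit pileups to the depth of each list gave the share of control peaks whose summit was expected to fall below that list's smallest −log10 p. Peaks were not called anew, so peak length and a new q cut are left out of this share, called the expected share missing. The expected share was 33.1% in siCHD3 against 35.4% observed, 12.2% in siCHD4 against 41.5%, 3.05% in siCHD5 against 21.5%, 24.2% in siMBD2 against 34.9%, and 41.6% in siMBD3 against 38.5%. Of the strongest decile of control peaks, 4.65% were expected to be missing in siCHD3 against 16.3% observed, 0.0781% in siCHD4 against 17.9%, 7.08e-06% in siCHD5 against 4.69%, 1.50% in siMBD2 against 13.2%, and 8.87% in siMBD3 against 17.2%. The expected shares hold no variation between libraries, and no replicate list was used to measure it. A gap between expected and observed shares therefore cannot be read as loss beyond depth.

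**Figure D2:**
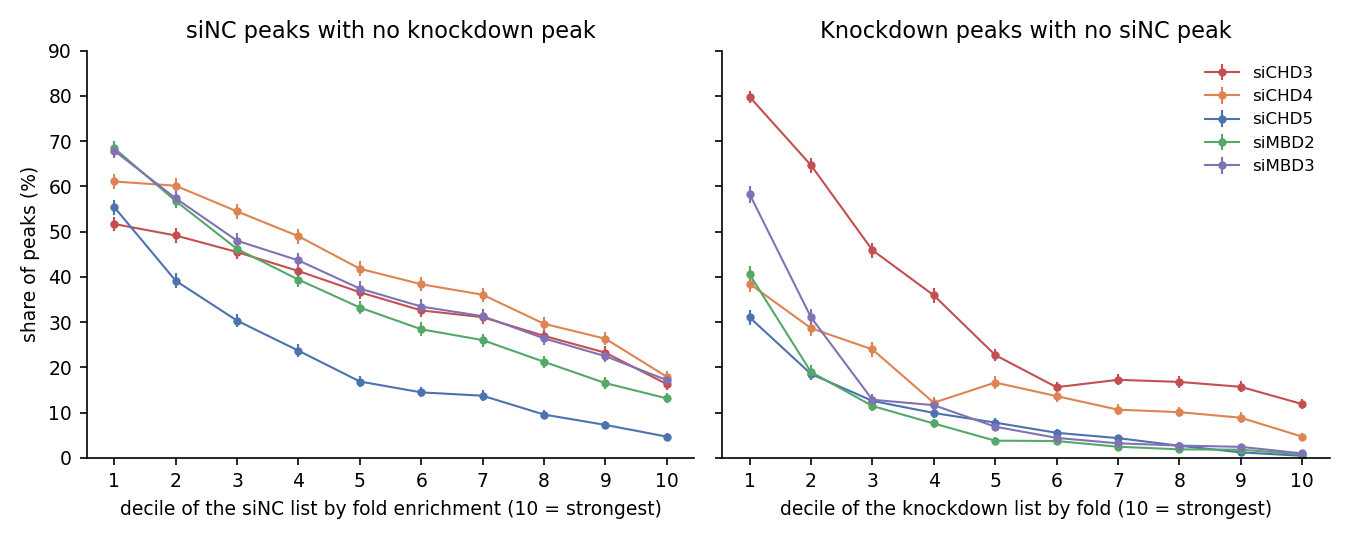
Left, the share of siNC peaks without a knockdown peak (%) by decile of siNC fold enrichment; right, the share of knockdown peaks without a siNC peak (%) by decile of each list's own fold. Points are 1 pooled list per knockdown and bars are exact 95% intervals for counting error; the missing share falls from the weakest to the strongest decile in all 5 lists, to 4.69% in siCHD5 and 17.9% in siCHD4.

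Control peaks with a knockdown partner had nearly the same summit in both lists. The median distance from a kept control summit to the nearest knockdown summit was 7 bp in siCHD5, 9 bp in siCHD4, 10 bp in siMBD2 and siMBD3, and 11 bp in siCHD3, and between 97.3% (siCHD3) and 99.2% (siCHD5) of these summits lay within 100 bp. Moving the knockdown peaks by 20000 bp reduced the share of control peaks with a partner to between 0.882% (siMBD3) and 1.41% (siCHD3). Missing peaks had been weaker in control, with median folds from 4.18 (siCHD5) to 4.71 (siCHD3), below the lowest median of 10000 random sets of control peaks of the same size in each comparison (lowest 5.13).

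Across the 6 lists, peaks merged into 54382 regions. Of these, 11811 regions (21.7%) were called in all 6 lists, 2882 in siNC alone and 8009 in siCHD3 alone. A further 2526 regions were called in all lists but siCHD4 and 1772 in all lists but siCHD3. Only 46 regions were called in all 5 knockdown lists and not in siNC, and 41 of them had no siNC peak within 1 kb. By median rank of fold, these were led by chromosome 6 from 32982530 to 32982891, chromosome 18 from 20611444 to 20611868 and chromosome 9 from 139962234 to 139962511. With −log10 q of at least 10 in all lists, 4765 regions were called in all 6.

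The 5 comparisons lost control peaks in common. Of the 36270 control peaks, 11834 (32.6%) were present in all 5 knockdown lists, with a median control fold of 6.10, and 2882 (7.95%) were absent from all 5, with a median fold of 4.06. Draws that kept each knockdown's rate of loss in every decile of control fold gave a mean of 546 peaks absent from all 5, with a maximum of 610 over 1000 draws, and independent lists would share 154. For pairs of knockdowns, the observed overlap of missing peaks was 1.25 to 1.69 times the drawn mean, lowest for siCHD4 with siCHD5 (4948 shared, drawn mean 3943, independent 3238) and highest for siCHD5 with siMBD2 (6171 shared, drawn mean 3650, independent 2727). All pairs share the 1 siNC list, so part of the excess may come from that list, and it could not be split. The draws were also matched on fold only, not on pileup. All knockdown lists had lower background coverage than siNC, so control peaks of low pileup may go uncalled in several lists together. The excess over the draws therefore does not separate a shared loss from shared power. The strongest control peaks with no peak of any knockdown within 1 kb lay on chromosome 3 from 122018726 to 122019027 (fold 11.9), chromosome 19 from 55979217 to 55979678 (fold 9.53) and chromosome 10 from 129362271 to 129362545 (fold 9.44).

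Losses were unevenly spread over chromosomes. Chromosomes 18, 13, 4 and 8 lost more control peaks than the mean of draws matched on fold in siCHD3, siCHD4, siMBD2 and siMBD3, and chromosomes 1 and 22 lost fewer. On chromosome 18 the missing share was 46.6% in siCHD3 against a matched mean of 33.3%, and 47.4% in siMBD3 against 35.7%. In siCHD5 it was 20.9% against 18.8%. On chromosome 22 the missing share was 30.7% in siCHD3 against a matched mean of 38.7%, and 32.6% in siMBD3 against 42.8%. Missing peaks also lay next to each other slightly more often than drawn ones: the next control peak was missing too for 38.0% of missing peaks in siCHD3 (drawn mean 35.7%), 43.7% in siCHD4 (41.8%), 25.4% in siCHD5 (22.4%), 36.8% in siMBD2 (35.6%) and 41.0% in siMBD3 (39.0%), with 0 of 10000 draws as high in each. Draws for chromosomes and adjacent peaks were matched on fold only. Control pileup and local background, which also set the chance of a call, were not matched in them, so power may account for part of both patterns.

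Loss also followed the density of control peaks, a relation examined only after the results by chromosome were seen. In the 20% of control peaks with the fewest other peaks within 500 kb, 43.1% were missing in siCHD3 against a mean of 33.6% in draws matched on fold, and in the 20% with the most, 28.9% against 37.4%. The siMBD3 list gave 45.5% against 36.1% and 32.8% against 41.1%, siCHD4 gave 48.1% against 39.1% and 36.5% against 43.9%, and siMBD2 gave 37.9% against 32.2% and 33.0% against 37.9%. In siCHD5 the sparsest quintile gave 20.3%, within the range of the draws (17.6 to 20.7). In a further 1000 draws per list, matching on the chance of a call at the knockdown's depth reduced the excess in the sparsest quintile from 9.56 to 6.24 percentage points in siCHD3, 8.90 to 4.49 in siCHD4, 9.47 to 5.77 in siMBD3 and 5.71 to 1.77 in siMBD2, and placed siCHD5 below its draws (21.04 to 23.17). Matching jointly on control pileup and local background left an excess of 4.55 points in siCHD3, 3.86 in siCHD4 and 3.20 in siMBD3, ended it in siMBD2 (37.9% against draws of 37.2 to 39.3) and placed siCHD5 below its draws (22.5 to 24.7). Without control peaks at wide siCHD3 or siCHD4 peaks, siCHD5 gave 19.9%, above its draws matched on fold (16.9 to 19.5).

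**Figure D3:**
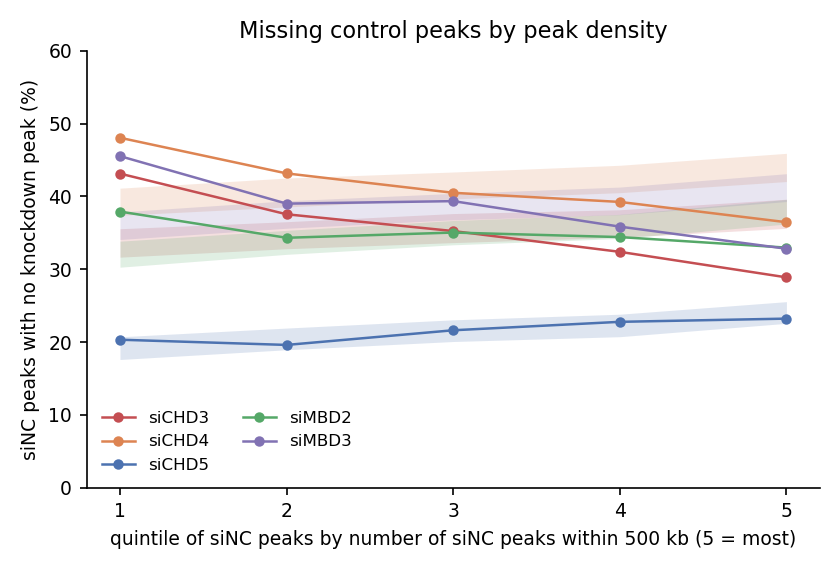
Lines give the share of siNC peaks without a knockdown peak (%) in quintiles of siNC peaks ordered by the number of other siNC peaks within 500 kb, and bands give the range of 10000 draws matched on siNC fold. In the sparsest quintile the share was 43.1% in siCHD3 and 20.3% in siCHD5, the latter inside its band for draws matched on fold.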

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

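Contigs outside chromosomes 1 to 22 and X, which are left out of the counts reported above, held a larger share of peaks in some knockdown lists than in siNC, and the rule on mitochondrial peaks was chosen only after their counts were seen. The hg19 haplotype copies of the major histocompatibility complex held 753 peaks in siCHD3 (2.13% of all its peaks, interval 1.98 to 2.29), 427 in siCHD4 (1.64%), 401 in siMBD3 (1.52%) and 364 in siMBD2 (1.36%), against 344 in siNC (0.933%, interval 0.838 to 1.04). The siCHD5 list held 337 there (1.05%, interval 0.943 to 1.17, which overlaps that of siNC). On the mitochondrial genome 9 peaks were called in siCHD4, 8 in siCHD3, 7 in siMBD3 and 2 in siMBD2, against 0 in siNC and 0 in siCHD5. Other unplaced or haplotype contigs held 206 peaks in siMBD2 (0.772%, interval 0.670 to 0.884), against 208 in the longer siNC list (0.564%, interval 0.490 to 0.646).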

How the results depend on the processing

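Of 102 alternatives to the 11 counts compared, 71 stayed within 1.5 times and 31 did not. Counts were compared, not shares, and the number of peaks behind them changes with the setting. At −log10 q of at least 10 in both lists, the counts missing in siCHD3 and siMBD3 stayed within 1.5 times. Their shares rose from 35.4% to 59.1% and from 38.5% to 61.2%. Reciprocal overlap, summit distance, a 1 kb window, all contigs and leaving out peaks over 1 kb moved no count they were run on beyond 1.5 times. Wider merging and leaving out siCHD3 or siCHD4 were run only on the regions called in all 6 lists, and kept that count within 1.5 times. Leaving out peaks over 1 kb or a list, like the weighting by depth, was chosen after seeing the data. Fewer peaks enter the stricter settings by construction. Lists of equal length give nearly equal numbers missing and added, also by construction. With −log10 q of at least 5 in both lists, added peaks numbered 4540 in siCHD3, 1743 in siCHD4, 890 in siMBD2 and 1056 in siMBD3. At 10 in both lists they numbered 2597, 900, 358 and 315 in that order, siCHD5 lacked 5174 control peaks, and 4765 regions were called in all 6 lists. At 10 in the searched-for list only, missing peaks were 8263 (siCHD3), 9808 (siCHD4), 2674 (siCHD5), 6597 (siMBD2) and 8067 (siMBD3), and added peaks 1264, 276, 900, 168 and 158. Lists of equal length gave 7678, 7727, 3339, 4857 and 6147 missing, and 7741 (siCHD4), 4798 (siMBD2) and 6072 (siMBD3) added. Weighting by the chance of a call at the knockdown's depth gave 6591 (siCHD3), 6769 (siMBD2) and 5249 (siMBD3) missing. Fewer control peaks were callable in these lists, and the share of them missing was also lower, at 27.2%, 24.6% and 24.8% in that order. In share missing, siCHD5 was lowest throughout, and siCHD4 highest except at −log10 q of at least 10 in both lists. All 10 regions ranked per knockdown had −log10 q of at least 10 in the list that held them. They were picked by highest fold, and their absence from the other list was not rechecked, so this says little about other settings. No paired analysis was possible because the lists used here pool the replicates, and leaving out a replicate was not run for the same reason. Single replicates were not analysed here. Promoter and motif windows were not run without an hg19 genome and annotation. Over all control peaks, thinning of the siNC summit pileups gave 41.6% expected missing in siMBD3, above the 38.5% observed, though its strongest decile lost 17.2% against 8.87% expected. In the other lists observed shares exceeded expected ones, which leave out variation between libraries.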

Other observations

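The comparison of siCHD4 with siMBD3, the ratio of deciles, background coverage, the overlap of wide peaks and the matching on control pileup and background are tests chosen only after the results were seen, as were the looks at peak width and at added peaks in common. Added peaks recurred between lists: 2267 added siCHD3 peaks overlapped an added siCHD4 peak. Both sets are defined by absence from the 1 siNC list, so sites not called there recur without any effect of a knockdown, and no value for that was computed. The overlap was 53.2% of the smaller set, against 14.1% (siCHD4 and siCHD5) to 25.8% (siCHD5 and siMBD2) in other pairs. Among added peaks with −log10 q of at least 10 the pair did not stand apart: siCHD3 and siCHD4 shared 59.4% of the smaller set, siCHD5 and siMBD2 58.9%, and siCHD5 and siMBD3 46.2%. The siCHD3 and siCHD4 lists held the most wide peaks. Peaks over 1 kb numbered 937 in siCHD3 and 353 in siCHD4, against 164 in siNC, 64 in siMBD3, 39 in siCHD5 and 33 in siMBD2, and 93.8% of those in siCHD3 overlapped a siCHD4 peak (interval 92.1 to 95.3). Among the strongest wide siCHD3 peaks were chromosome 2 from 38708913 to 38709992 (fold 138, rank 6 in its list) and chromosome 1 from 236646392 to 236647841 (fold 134, rank 7). Both regions were called in all 6 lists, with siNC folds of 13.2 and 14.5. Of the 164 wide siNC peaks, 158 overlapped a wide siCHD3 peak.

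These wide peaks were weighed against 3 explanations. Deeper sequencing is argued against, since siCHD3 had 0.150 times the background coverage of siNC with shortest peaks of 196 and 186 bp. Sites bound only after the knockdown cannot be the whole cause, because 81.4% of wide siCHD3 peaks overlapped a siNC peak (interval 78.8 to 83.9). A lower local background is argued against as the whole cause at 158 regions wide in both lists. Pileup per coverage relative to siNC was there 4.60 times that at ordinary shared regions (bootstrap interval over regions 4.32 to 4.81). The same ratio was 2.23 in siCHD4 (141 regions), 1.17 in siMBD2 (27), 1.16 in siMBD3 (53) and 0.460 in siCHD5 (29), each over its own regions. Only 16.3% of wide siCHD3 peaks overlapped a wide siNC peak, so most were not covered. Median background at wide siCHD3 peaks was 1.78 times the lowest of that list, against 2.59 for all its peaks (2.88 against 3.48 in siNC). A lower background thus stays open as part of the cause. A gain of CTCF signal after loss of CHD3 or CHD4, a difference in library preparation, and carry-over of other DNA such as plasmid or exon-like sequence, which was not analysed here, remain open and may not be separable with 1 pooled list per condition.

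For the missing control peaks, depth as the whole cause of the differences between knockdowns is argued against, because siCHD4 lacked 2.97 percentage points more control peaks than siMBD3 although its background coverage was higher (1.06 against 0.374, with shortest peaks of 186 and 178 bp). That difference turned round at −log10 q of at least 10 in both lists (59.4% against 61.2%), a setting that asks more of the list of lower coverage. Each share comes from 1 pooled list, so variation between libraries of a condition, not measured here, could also lie behind the difference. The share missing in the weakest decile was at least 3.17 times that in the strongest (siCHD3) and up to 11.8 times (siCHD5). Deciles rank peaks by fold, not by distance from the calling threshold, so this ratio cannot decide whether peaks near it dropped out. Control −log10 q was at least 10 for 8263 of 12856 missing peaks in siCHD3 and 9808 of 15047 in siCHD4. It was so for 2674 of 7805 in siCHD5, 6597 of 12672 in siMBD2 and 8067 of 13970 in siMBD3. These q-values belong to siNC and do not give nearness to a knockdown list's threshold. Loss of peaks near the threshold thus stays open. Depth as part of the cause and a real loss of CTCF binding stay open in every list. Lower enrichment was not seen in pileup per coverage at ordinary regions called in both lists, which was 1.06 (siCHD4) to 1.78 (siMBD3) times that of siNC. Median fold at shared peaks was lower than that of their siNC partners in siCHD4 (5.20 against 5.65) and higher in the other knockdown lists. Fold adds 1 to pileup and to background, so it shifts with coverage and cannot decide this. Regions not called in a knockdown list are left out of both values, so lower enrichment stays open too.

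Higher loss where control peaks are sparse was tested against power and wide peaks. With draws matched on the chance of a call at the knockdown's depth, the excess in the sparsest quintile was 6.24 percentage points in siCHD3, 5.77 in siMBD3, 4.49 in siCHD4 and 1.77 in siMBD2, and siCHD5 was reversed, at 20.3% against a drawn range of 21.04 to 23.17, but this matching rests on modelled thinning. Matching on control pileup and local background, without that model, left at least 3.20 points in siCHD3, siCHD4 and siMBD3, above the range of 1000 draws, so power set by these is unlikely to be the whole cause there, while siMBD2 gave -0.316 and power stays open for it. Without control peaks at wide siCHD3 or siCHD4 peaks, the excess in siCHD3 was 9.20 points in draws matched on fold. A control peak at a wide siCHD3 peak is present in siCHD3 by definition, so this step removes mainly peaks that are not missing. It therefore cannot decide whether wide peaks play a part, and they stay open. The local background of the knockdown lists at missing peaks, base composition, neither analysed here, and a biological effect of the knockdowns stay open.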
